A study of Xenopus tropicalis with 12 samples.

How the data were processed

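Liver RNA of wild-type *Xenopus tropicalis* was sequenced from 12 samples in 4 groups of 3: untreated tadpoles at stages 54, 61 and 66 (st54, st61 and st66), and stage 54 tadpoles kept in 10 nM triiodothyronine (T3, the active thyroid hormone) for 18 h (T3). Per the labels, the tadpoles came from the same parents and the 3 samples of a group from different tadpoles. RNA was taken up on RNeasy columns and libraries were sequenced on an Illumina instrument, per the labels' protocols. The authors deposited a table of raw read counts per gene, 1 column per library, and these counts were used as deposited. Trimming with cutadapt 3.4 and alignment with STAR 2.7.8a are named in the submitters' processing notes, and the column names, per the file headers, are those of alignments that had been trimmed and had duplicates marked. The genome build, the annotation, the strand setting and whether marked duplicates were dropped before counting are not given in the sources used here. Reads of overlapping genes on opposite strands, and of near-identical copies such as the globins, trypsins, elastases and tandem cytochrome P450 genes, could therefore have been split or merged, and values of such genes are uncertain.

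The table listed 26529 genes. Lines of 2 genes (otogl2 and neb) were broken over 6 lines and were left out. 26528 symbols matched a reference table of gene names for the UCB_Xtro_10.0 assembly, and the start and end of 26288 genes (99.1%) equalled those of that assembly. Coordinates are printed as the deposited table gives them. No gene in the table lay on a sequence named MT, chrM, ChrM or chrMT, so no mitochondrial share was computed. Symbols were not searched, so mitochondrial genes under another sequence name would have been missed. No genome sequence was used, so GC content was not checked. 5575 genes had no count in any library. Totals ran from 7928459 to 39536147 counts per library. A count of 3, taken as the floor, was worth between 0.0759 CPM in the deepest library and 0.378 CPM in the shallowest. Counting intervals of ratios and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Intervals of medians over sets of genes come from resampling the genes.

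Counts were normalised by TMM factors and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr by group left 15102 genes, and a quasi-likelihood model with robust settings was fitted once to all 12 libraries, with 4 group means and 8 residual degrees of freedom. The comparisons were st61 vs st54, st66 vs st54, st66 vs st61, T3 vs st54 and T3 vs st61. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Levels are CPM on TMM-scaled library sizes, as mean ± SD over 3 libraries, and folds are edgeR's. Genes above st54 at st61 and lower again at st66 were counted as peaking, and the opposite as having a trough. 34 gene lists (pathways, complexes and markers of liver and of neighbouring or circulating cells) were written before the data were examined and tested with camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists of a comparison, and again with an estimated correlation and with fry. In every comparison some wrong groupings of the libraries took as many lists past camera's threshold as the real one. The number of camera calls alone therefore does not set the groups apart. Members of a list were also counted after adjustment over the list alone.

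Genes to name were fixed by a rule written at the same time: in each comparison the 6 largest called increases and 6 largest called decreases (3 and 3 for T3 vs st61) with a mean of at least 10 CPM in the higher group, no overlap of libraries and a gene symbol; up to 3 called members, by adjusted p, of each core list and each list past camera's threshold, or the most abundant member, as a value only, where no member was called; thra, thrb, klf9, dio3, cps1, arg1, alb and pcna in every comparison; and the 5 strongest peaks and 5 strongest troughs. Some names the rule gives are left out. The fit was tested on simulated data: in counts drawn for st61 vs st54 with 200 of 15102 genes changed, it recovered 20% of 2-fold and 80% of 4-fold changes, with 100 true and 6 false calls. That simulation gave all groups the same spread per gene, unlike the libraries (biological coefficient of variation 33.5% in st54 and 2.6% in T3). Its false calls therefore do not show how a joint error over such unequal groups affects the calls. A seeded list gave a camera p of 1.8e-114 and a random list 0.39. The seeded list held only genes that had been raised, so its p was close to fixed beforehand. Genes were drawn independently, unlike those of real lists (estimated correlation 0.884 for mitosis in st61 vs st54). These 2 values therefore do not show how often camera errs at the preset correlation.

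Alternatives fixed beforehand were DESeq2 1.42.0, RLE and upper-quartile factors, no low-count filter, the replicate number as a block, only the groups compared, the 20 most abundant genes left out, estimated correlation and fry for lists, and each library left out in turn. Chosen after seeing the data were the T3 libraries summed to 1, a correction for exonic length, all libraries thinned to the smallest total, and stage 66 represented by replicate 1 alone. Overlap between comparisons that share the st54 libraries was set against 20 simulations with no effect. Data were handled and plotted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.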

Results

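The series followed the liver of *Xenopus tropicalis* through metamorphosis, and asked which of its changes 18 h of T3 brings about in a premetamorphic tadpole. Stage 54 precedes the rise of endogenous thyroid hormone, stage 61 lies at the climax of metamorphosis, and stage 66 is its end. Total counts were 23308776, 29387091 and 12481902 in st54 replicates 1 to 3, 18966115, 21060693 and 18641714 in st61, 19812786, 7928459 and 8506341 in st66, and 39536147, 31745665 and 27665558 in T3. Between 16272 and 18922 genes were detected per library. The most abundant genes over all libraries were tf, alb and c3, which encode transferrin, albumin and complement C3 and are secreted by hepatocytes.

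The groups differed in how far their libraries lay apart. The biological coefficient of variation was 33.5% in st54, 23.9% in st61, 40.3% in st66 and 2.6% in T3. Chi-square per gene between pairs of T3 libraries was 1.99 to 5.56, above sampling noise, against 14.3 to 175 in the other groups. That value does not tell separate animals from repeat libraries of 1 RNA pool. The T3 libraries were kept as the 3 samples that the labels give, and the counts of T3 calls are also given with them summed. The spread is estimated jointly over the 4 groups, so the T3 libraries also enter the error of the stage comparisons. In st66, replicates 2 and 3 had the smallest totals and the largest shares of ribosomal protein reads (16.0% and 16.3%), against 7.71% in replicate 1. The labels give stage 66 for all 3, but replicate 1 lay near the st61 libraries on the first 2 principal components (34.4 and -31.4, against 70.7 and 37.1 in replicate 2 and 67.4 and 47.2 in replicate 3). mki67, a proliferation marker, was at 124 CPM in st66 replicate 1 and at 17.1 and 14.5 CPM in replicates 2 and 3, against 51.4 to 57.1 CPM in st61. Means and counts for st66 therefore cover libraries that differ in these respects. In st54, the baseline of the other groups, replicate 3 stood apart. Its Spearman correlation across genes, which are not independent replicates, was 0.941 and 0.943 with replicates 1 and 2 and 0.953 to 0.954 with the T3 libraries, and its ribosomal share was 12.5%, against 9.45% and 8.56% in replicates 1 and 2. The first principal component (41.8% of variance) put st54 and T3 on one side and st61 and st66 on the other.

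**Figure D1:**
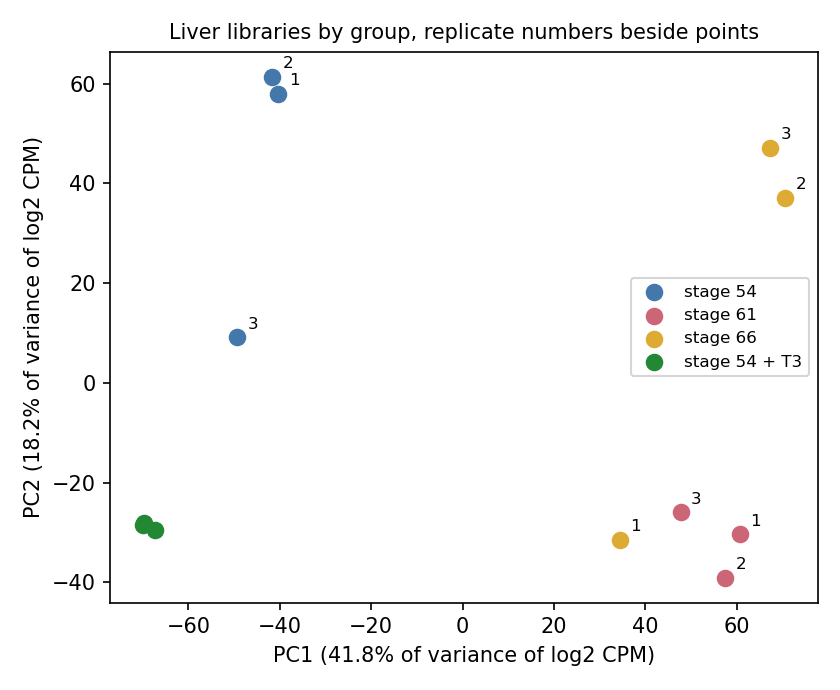
Principal components of log2 CPM for the 12 libraries, PC1 (41.8% of variance) on the x axis and PC2 (18.2%) on the y axis, with 1 point per library, coloured by group. The 3 T3 points nearly coincide, st54 replicate 3 (9.17 on PC2) lies apart from replicates 1 and 2 (58.0 and 61.4), and st66 replicate 1 lies near st61.

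**Figure D2:**
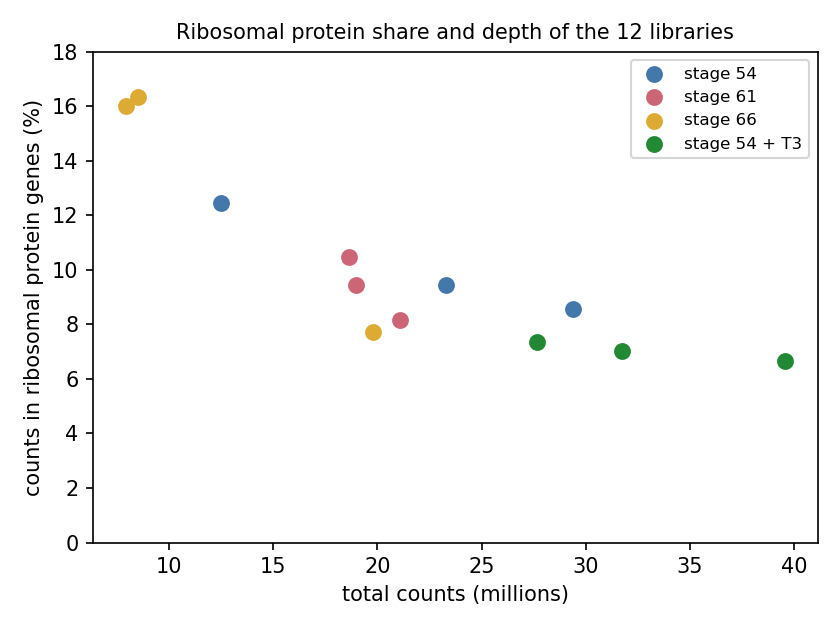
Share of counts in cytosolic ribosomal protein genes (y axis, %) against total counts (x axis, in units of 1e+06), 1 point per library, coloured by group. The share runs from 6.66% in the deepest library to 16.3% in 1 of the 2 shallowest.

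Between stage 54 and stage 61 the liver raised thyroid hormone response genes. thrb, the hormone-inducible receptor gene (chromosome 6, 46687270 to 46933187), rose from 1.02 ± 0.551 to 19.5 ± 2.27 CPM (mean ± SD, n = 3, as throughout; 17.8-fold, adjusted p = 5.76e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as throughout). thibz, a leucine zipper gene induced by the hormone in tadpoles (chromosome 3, 140193605 to 140202878), rose from 1.16 ± 1.49 to 361 ± 58.4 CPM, and nfic, which encodes a transcription factor of the NFI family, rose from 4.39 ± 0.989 to 226 ± 15.1 CPM. dio2, the deiodinase that makes T3 from its precursor, rose 11.6-fold, while dio3, the deiodinase that inactivates the hormone, fell from 794 ± 290 to 12.8 ± 1.46 CPM (adjusted p = 0.000164). Of 11 direct response genes 8 rose and 1 (dio3) fell, the same counts adjusted over the list alone, and the list stood above other genes (camera adjusted p = 2.46e-05, and adjusted p = 0.028 with an estimated correlation). thra, the receptor gene present before the hormone rises, was at 4.42 ± 1.31 and 4.10 ± 0.793 CPM (adjusted p = 0.975).

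Single genes of the urea cycle and plasma protein lists moved in both directions at stage 61. cps1, the entry enzyme of the urea cycle (chromosome 9, 56844485 to 56902762), rose from 1524 ± 373 to 6881 ± 1670 CPM (4.52-fold, adjusted p = 0.000166), whereas arg2, a mitochondrial arginase, and glud1, glutamate dehydrogenase, fell 19.3-fold and 2.73-fold. Of 17 urea cycle and nitrogen genes 4 rose and 4 fell (5 and 5 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.839). Among 50 plasma protein genes 11 rose and 2 fell (12 and 3 adjusted over the list alone, camera adjusted p = 0.051). With an estimated correlation the list had adjusted p = 0.95, and with fry 0.12. It passed, higher, with upper-quartile factors (adjusted p = 0.048), without the low-count filter (0.034), and with the replicate block (0.05 after rounding). It also passed without the 20 most abundant genes (0.017), with st66 replicate 1 alone (0.043), in thinned libraries (0.039) and with the length correction (0.0074), and without st54 replicate 2 (0.0093), st61 replicate 3 (0.019) or st66 replicate 1 (0.046) or 2 (0.048). apoe, an apolipoprotein, rose from 3.18 ± 1.64 to 87.0 ± 54.7 CPM and proc, anticoagulant protein C, rose 3.52-fold, while ttr, the thyroid hormone carrier transthyretin, fell 6.97-fold. alb stood at 10730 ± 1110 and 12280 ± 1570 CPM (adjusted p = 0.687).

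The globins changed in both directions. hba1 rose from 235 ± 86.7 to 3000 ± 344 CPM and hbg1 from 203 ± 97.3 to 3232 ± 328 CPM, whereas hbe1 fell from 39.6 ± 17.4 to 0.351 ± 0.248 CPM. Of 12 globin genes 3 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.714), and the list of other erythroid genes did not pass (camera adjusted p = 0.667). Globin genes lie in clusters of near-identical copies, so their single values are uncertain.

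Sterol and energy metabolism genes fell at stage 61. Of 26 cholesterol synthesis genes 22 fell (25 adjusted over the list alone), among them sqle, squalene epoxidase, from 60.1 ± 55.6 to 0.335 ± 0.308 CPM, ebp, a sterol isomerase gene, 8.87-fold, and dhcr7, which encodes the reductase of the last step, 3.7-fold (list: camera adjusted p = 7.99e-12, and adjusted p = 0.4 with an estimated correlation). cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 6, 116352903 to 116357128), fell from 1105 ± 872 to 0.459 ± 0.258 CPM (adjusted p = 0.000183), and of 20 bile acid genes 4 rose and 8 fell (5 and 11 adjusted over the list alone, camera adjusted p = 0.156). Of 29 fatty acid oxidation and ketogenesis genes 12 fell (16 adjusted over the list alone), including pdk4, a kinase that restrains pyruvate oxidation, 6.41-fold, and cpt1a, the carnitine palmitoyltransferase of the outer membrane, 3.58-fold (camera adjusted p = 2.99e-06, and adjusted p = 0.25 with an estimated correlation). Of 70 nuclear genes of the respiratory chain 34 fell (50 adjusted over the list alone), with cox7c, a cytochrome oxidase subunit, at 176 ± 40.1 and 86.0 ± 9.73 CPM (camera adjusted p = 3.11e-15, and adjusted p = 0.83 with an estimated correlation). ucp1, a mitochondrial uncoupling protein, fell from 99.0 ± 39.7 to 0.234 ± 0.0483 CPM.

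Connective tissue genes rose. Of 35 stellate cell and fibroblast markers 21 rose (25 rose and 1 fell adjusted over the list alone): col6a1 and col6a2, chains of collagen VI, rose 4.66-fold and 6.14-fold, and fbn1, fibrillin, rose 8.34-fold (camera adjusted p = 7.99e-12, and adjusted p = 0.23 with an estimated correlation). Of 24 matrix remodelling genes 13 rose and 1 fell, the same counts adjusted over the list alone, with mmp2, a gelatinase, from 3.64 ± 1.11 to 30.4 ± 8.44 CPM (camera adjusted p = 3.09e-06, and adjusted p = 0.028 with an estimated correlation). Of 29 endothelial markers 7 rose and 1 fell (9 and 1 adjusted over the list alone), cldn5, a tight junction gene, rising 3.09-fold (camera adjusted p = 0.00702, and adjusted p = 0.95 with an estimated correlation). That call ended with fry (adjusted p = 0.097) and without st54 replicate 3 (adjusted p = 0.053) or st61 replicate 2 (adjusted p = 0.055). Of 60 Wnt genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), led by lrp5, a co-receptor (5.13-fold), dkk3 (16.9-fold) and axin2, a feedback target of the pathway, from 0.777 ± 0.47 to 29.1 ± 17.8 CPM (camera adjusted p = 0.00365, and adjusted p = 0.73 with an estimated correlation).

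A few genes of dividing cells fell. Of 46 mitosis genes 4 fell (3 adjusted over the list alone), such as cenpa, the centromeric histone, 2.43-fold (camera adjusted p = 0.000398, adjusted p = 0.95 with an estimated correlation, fry adjusted p = 0.447). pcna, the replication clamp, fell 1.7-fold, and of 45 DNA replication genes 4 fell (2 adjusted over the list alone, camera adjusted p = 0.051). The DNA replication list had adjusted p = 0.95 with an estimated correlation and a fry adjusted p of 0.617. It passed, lower, with RLE (adjusted p = 0.049) or upper-quartile factors (0.048), without the low-count filter (0.041), with the replicate block (0.041), without the 20 most abundant genes (0.048), in thinned libraries (0.038), with the T3 libraries summed (0.044) and with st66 replicate 1 alone (0.0031). It also passed without st54 replicate 3 (0.021), st61 replicate 1 (0.029) or 3 (0.044), or st66 replicate 1 (0.0046), 2 (0.042) or 3 (0.048). Lists that did not pass at stage 61 were, by camera adjusted p, hormone receptors and coregulators (0.557), complement (0.839), lipogenesis (0.714), gluconeogenesis and glycogen (0.156, and 0.021, lower, without st61 replicate 1), amino acid breakdown (0.131, and 0.021, lower, without st61 replicate 1), endoplasmic reticulum folding (0.667), hepatocyte transcription factors (0.824), apoptosis (0.691), immediate early and heat shock genes (0.618), antigen presentation (0.618), ribosomal proteins (0.692) and hepatic detoxification (0.399). Of marker lists, myeloid cells (0.839), lymphocytes (0.618), bile duct (0.408), exocrine pancreas (0.714), intestinal epithelium (0.667), pigment cells (0.501) and skeletal muscle (0.824) did not pass either. Of 22 exocrine pancreas genes 5 rose and 3 fell (5 and 4 adjusted over the list alone). Pancreatic enzyme genes were among the largest increases: try10, a trypsin, rose from 0.0964 ± 0.131 to 56.2 ± 74.1 CPM, and the elastases cela1.4 from 0.148 ± 0.227 to 77.3 ± 94 CPM, ela3b from 0.109 ± 0.067 to 66.6 ± 57.2 CPM and cela1.2 from 0.246 ± 0.288 to 101 ± 108 CPM. Values of these near-identical copies are uncertain.

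In all, 1516 genes were higher and 1337 lower at st61 than at st54, 1101 and 811 of them by at least 2-fold. With the T3 libraries summed the counts were 1010 and 649. The lower count was 868 without st54 replicate 2, 889 without st61 replicate 1, 658 without st61 replicate 2, 2238 without st66 replicate 1, and 2219 with st66 replicate 1 as the only library of its stage.

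**Figure D3:**
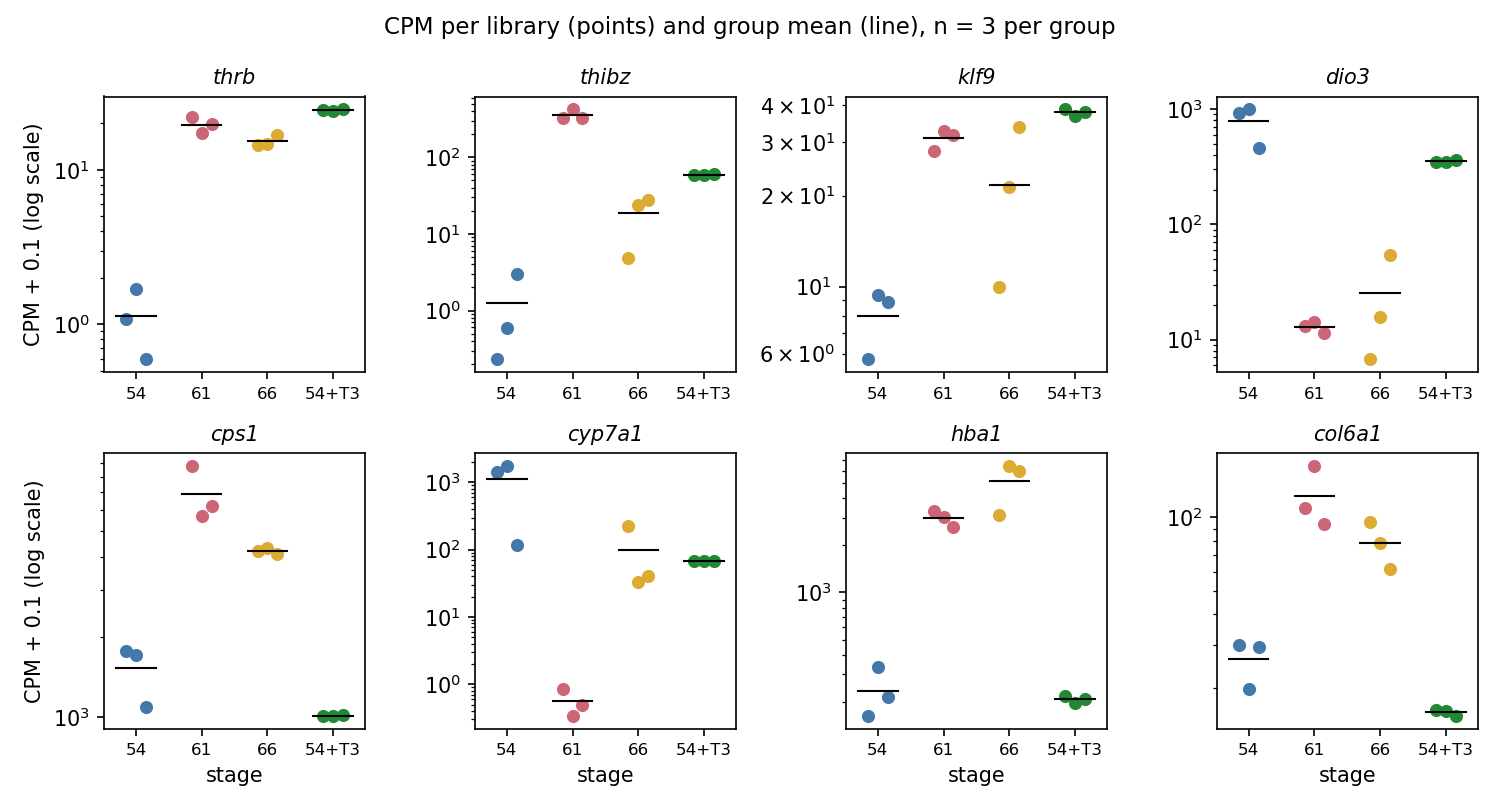
CPM plus 0.1 on a log scale for 8 genes, 1 point per library, with the group mean as a line (n = 3 per group), at stages 54, 61 and 66 and at stage 54 with T3. thrb and klf9 are higher at stage 61 and with T3 than at stage 54, cps1, hba1 and col6a1 are higher at stages 61 and 66 than at stage 54, and cyp7a1 is lowest at stage 61.

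At the end of metamorphosis part of this pattern stood. thrb was at 15.2 ± 1.28 CPM in st66 (13.8-fold above st54, adjusted p = 1.43e-05), nfic at 137 ± 9.42 CPM (31.5-fold) and dio3 at 25.3 ± 25.1 CPM (31.7-fold lower). Of the 11 direct response genes 5 were higher and 1 lower, the same counts adjusted over the list alone (camera adjusted p = 0.0389, and adjusted p = 0.54 with an estimated correlation). The list missed the threshold without st54 replicate 2 (adjusted p = 0.064), without st66 replicate 1 (0.18) and with st66 replicate 1 alone (0.078). hba1 and hbg1 reached 5190 ± 1800 and 6092 ± 2390 CPM, and hbe1 was at 0.165 ± 0.248 CPM. 4 of 12 globins were higher and 3 lower, the same counts adjusted over the list alone (camera adjusted p = 0.827). cps1 stood at 4207 ± 98.5 CPM (2.76-fold above st54, adjusted p = 0.00278, and adjusted p = 0.069 when only the st54 and st66 libraries were fitted). Of the urea cycle list 2 genes were higher and 5 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.164). apoe reached 254 ± 103 CPM and ttr stayed low at 124 ± 26.7 CPM, with 5 of 50 plasma protein genes higher and 3 lower (5 and 4 adjusted over the list alone, camera adjusted p = 0.439).

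Cholesterol synthesis, fatty acid oxidation, amino acid breakdown, gluconeogenesis and respiratory chain lists were lower than at stage 54. Of 26 cholesterol synthesis genes 7 were lower (14 adjusted over the list alone), insig1, a sterol sensor, falling 9.56-fold (camera adjusted p = 4.07e-09, and adjusted p = 0.54 with an estimated correlation). Of 29 fatty acid oxidation genes 8 were lower (9 adjusted over the list alone), pdk4 by 2.43-fold (camera adjusted p = 0.000453, and adjusted p = 0.54 with an estimated correlation). In amino acid breakdown 4 of 45 genes were higher and 11 lower (5 and 13 adjusted over the list alone): bhmt and gnmt, methyltransferases of methionine metabolism, rose 10.6-fold and 3.01-fold, and amt, of glycine cleavage, fell 2.95-fold. That list had a camera adjusted p of 0.00128 (adjusted p = 0.54 with an estimated correlation, and 0.071 without st66 replicate 1). In gluconeogenesis and glycogen 1 gene of 19 was higher and 4 lower (1 and 5 adjusted over the list alone), among them fbp1, fructose bisphosphatase, 3.15-fold (camera adjusted p = 0.033, and adjusted p = 0.55 with an estimated correlation). The list missed the threshold without st54 replicate 1 (adjusted p = 0.051), st54 replicate 2 (0.084) or st66 replicate 1 (0.12), and with st66 replicate 1 alone (0.08). Of 70 respiratory chain genes 2 were lower (adjusted over the list alone 0 in edgeR, with 16 at an unadjusted p under 0.05 and 8 by DESeq2 over all genes). The list was lower (camera adjusted p = 5.04e-06, adjusted p = 0.8 with an estimated correlation, fry adjusted p = 0.286, 0.056 without st54 replicate 3, 0.071 without st66 replicate 1). Lipogenesis (2 of 28 higher and 2 lower, 8 and 2 adjusted over the list alone, camera, higher, adjusted p = 0.584) did not pass. Nor did bile acid genes (4 of 20 higher and 1 lower, 4 and 2 adjusted over the list alone, camera, lower, adjusted p = 0.584, with a mean log2 change of 0.27 in the other direction).

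Fibroblast and pigment cell markers were higher, as were the Wnt and antigen presentation lists. 15 of 35 fibroblast markers were higher (21 higher and 2 lower adjusted over the list alone), col3a1, a fibrillar collagen, rising from 124 ± 25 to 558 ± 106 CPM (camera adjusted p = 9.19e-06, and adjusted p = 0.54 with an estimated correlation). Of 60 Wnt genes 9 were higher and 3 lower (12 and 4 adjusted over the list alone), again with lrp5, dkk3 and axin2 (camera adjusted p = 0.0469, adjusted p = 0.8 with an estimated correlation, 0.08 without st54 replicate 1, 0.11 without st54 replicate 2, 0.52 without st66 replicate 1, 0.051 in thinned libraries). Of 10 pigment cell genes 4 were higher and 1 lower (5 and 1 adjusted over the list alone): gpnmb, a melanosome and macrophage glycoprotein, rose from 8.70 ± 5.61 to 179 ± 65.2 CPM, and mitf, the pigment lineage regulator, rose 3.1-fold (camera adjusted p = 0.0224, and adjusted p = 0.54 with an estimated correlation). The pigment list missed the threshold without st54 replicate 2 (adjusted p = 0.18) or st66 replicate 1 (0.071), with st66 replicate 1 alone (0.22) and in thinned libraries (0.055). The antigen presentation list was higher (3 of 15 genes, 5 adjusted over the list alone; camera adjusted p = 0.041, adjusted p = 0.8 with an estimated correlation), and missed the threshold without st54 replicate 3 (0.4), st66 replicate 1 (0.055) or st66 replicate 2 (0.12), and with st66 replicate 1 alone (0.42). With fry the Wnt (adjusted p = 0.051) and antigen presentation (0.057) calls ended. Marker lists that did not pass were, by camera adjusted p, endothelial (lower, 0.118) and lymphocytes (lower, 0.138, with 3 of 26 genes lower, also 3 adjusted over the list alone), erythroid (0.501) and myeloid cells (0.977), bile duct (0.31), intestinal epithelium (0.584) and skeletal muscle (0.411). The endothelial list passed without st54 replicate 3 (adjusted p = 0.047) or st66 replicate 1 (0.033). Lymphocytes passed without st54 replicate 3 (0.0064), erythroid cells without st66 replicate 1 (0.045), myeloid cells without st54 replicate 1 (0.036) and skeletal muscle without st66 replicate 2 (0.013). Of other lists, complement (lower, camera adjusted p = 0.0575) passed with the replicate block (0.038), without the 20 most abundant genes (0.038), in thinned libraries (0.05 after rounding), with the length correction (0.047) and without st54 replicate 3 (0.00061) or st66 replicate 2 (0.023). Endoplasmic reticulum folding (0.138) passed, higher, without st54 replicate 3 (0.0064) or st66 replicate 3 (0.015) and with st66 replicate 1 alone (0.00038), and matrix remodelling (0.138) with fry (0.016) and without st66 replicate 3 (0.044). Plasma proteins passed with st66 replicate 1 alone (0.027), and hepatocyte transcription factors (0.34) and hepatic detoxification without st54 replicate 3 (0.035 and 0.017).

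Exocrine pancreas genes moved both ways: of 22, 4 were higher and 8 lower (4 and 11 adjusted over the list alone; camera, lower, adjusted p = 0.00984, and adjusted p = 0.8 with an estimated correlation). ela3b, an elastase, rose from 0.109 ± 0.067 to 37.9 ± 41.4 CPM, while cpb1, a carboxypeptidase, fell from 302 ± 287 to 9.81 ± 7.22 CPM. The list call ended with fry (adjusted p = 0.286) and without st54 replicate 3 (0.063) or st66 replicate 1 (0.2). slc38a4, an amino acid transporter, fell from 228 ± 103 to 0.878 ± 0.835 CPM, and ptger3, a prostaglandin receptor, from 148 ± 36.6 to 0.818 ± 0.863 CPM.

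Camera placed mitosis (adjusted p = 1.05e-08) and DNA replication (0.033) below st54 and ribosomal proteins above (0.000114), with adjusted p = 0.8 for each with an estimated correlation and fry adjusted p of 0.199, 0.506 and 0.395. Few members passed. 2 of 46 mitosis genes were lower (adjusted over the list alone 0 in edgeR, with 7 at an unadjusted p under 0.05 and 4 by DESeq2 over all genes). 1 of 45 DNA replication genes was higher, also 1 adjusted over the list alone. Of 76 ribosomal protein genes 0 passed in edgeR, over all genes or adjusted over the list alone (1 higher at an unadjusted p under 0.05, 0 by DESeq2). The directions turned with st66 replicate 1 alone, for mitosis (adjusted p = 1.3e-05), DNA replication (2e-07) and ribosomal proteins (5.2e-11). A single library leaves the group no spread of its own and is assumed to vary like the other groups, so these p-values describe that library and not the stage. The DNA replication call also ended without st54 replicate 1 (adjusted p = 0.074), st54 replicate 2 (0.14), st66 replicate 2 (0.36) or st66 replicate 3 (0.58) and without the low-count filter (0.051), and the ribosomal call without st66 replicate 2 or 3 (0.1 each). pcna was at 121 ± 14.2 CPM in st66 (adjusted p = 0.955 against st54).

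At both st61 and st66, 670 genes were higher and 497 lower than at st54. Both comparisons use the same st54 libraries, whose spread pushes changes to the same sign. How much of this overlap the shared libraries bring was not estimated, and the overlap was not counted under other settings. In all, 1243 genes were higher and 827 lower at st66 than at st54. Fitted without the other groups the counts were 296 and 271, and with the T3 libraries summed 591 and 477, while DESeq2 gave 1249 lower. The higher count was 712 without st54 replicate 1 and 785 without st54 replicate 2, the lower count was 1323 without st54 replicate 3, and both grew, to 2333 and 1899, without st66 replicate 1.

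From stage 61 to stage 66 some of the genes high at the climax fell. thibz fell from 361 ± 58.4 to 18.5 ± 12.1 CPM (adjusted p = 0.0062), bcl6, a transcriptional repressor, from 88.5 ± 13.3 to 10.1 ± 3.91 CPM, and dio2 2.79-fold. thrb and klf9 did not pass (adjusted p = 0.359 and 0.34), except klf9 with st66 replicate 1 alone (0.0051). Of the 11 direct response genes 4 fell (1 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.00153, and adjusted p = 0.1 with an estimated correlation). cyp7a1 rose from 0.459 ± 0.258 to 99.7 ± 108 CPM, bbox1, of carnitine synthesis, 16.2-fold, and sult2b1, a sterol sulfotransferase, 19.6-fold. gls2, liver glutaminase, fell from 71.3 ± 26.9 to 9.15 ± 3.19 CPM.

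Plasma protein, matrix and endothelial lists were lower at st66 than at st61. Of 50 plasma protein genes 12 fell and 1 rose (16 and 3 adjusted over the list alone), f12, a clotting factor, falling 2.69-fold (camera adjusted p = 0.00153, adjusted p = 0.86 with an estimated correlation, 0.22 without st66 replicate 1). Of 24 matrix remodelling genes 5 fell (10 adjusted over the list alone), with adamts5, an aggrecanase, 4.51-fold (camera adjusted p = 9.61e-05, and adjusted p = 0.1 with an estimated correlation). Of 29 endothelial markers 6 fell (8 adjusted over the list alone): cldn5 fell 2.8-fold and lyve1, a lymphatic and sinusoidal receptor, from 155 ± 38.4 to 39.6 ± 19.9 CPM (camera adjusted p = 1.95e-06, and adjusted p = 0.79 with an estimated correlation). Fibroblast markers (3 of 35 lower and 1 higher, 10 and 1 adjusted over the list alone, camera adjusted p = 0.000249) and exocrine pancreas genes (3 of 22 lower, 10 adjusted over the list alone, camera adjusted p = 0.000361) were lower, with adjusted p = 0.79 and 0.86 with an estimated correlation, and the latter missed the threshold without st66 replicate 1 (0.1). In the complement list 1 of 20 genes (c2) was higher and 1 (fcn1) lower, the same counts adjusted over the list alone. Camera placed the list lower (adjusted p = 0.0144, adjusted p = 0.86 with an estimated correlation, 0.071 without st61 replicate 1, 0.11 without st66 replicate 1) and antigen presentation higher (3 of 15 genes, 7 adjusted over the list alone, adjusted p = 0.00153, adjusted p = 0.79 with an estimated correlation, 0.12 with st66 replicate 1 alone). With fry the plasma protein (adjusted p = 0.0923), fibroblast (0.0826), exocrine pancreas (0.27) and complement (0.233) calls ended.

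Skeletal muscle markers were uneven among the st66 libraries. Of 16, 1 (acta1) was higher and 1 (cacna1s) lower than at st61 (12 and 1 adjusted over the list alone), with a median log2 change of 3.73, and the list did not pass (camera adjusted p = 0.3, adjusted p = 0.91 with an estimated correlation, fry adjusted p = 0.66). It passed, higher, without st66 replicate 2 (adjusted p = 0.0044) and with the T3 libraries summed (0.04). ckm, muscle creatine kinase, was at 7.15, 2.53 and 282 CPM in st66 replicates 1 to 3 and acta1, skeletal actin, at 10.6, 0.169 and 122 CPM, against 3.13 to 6.37 and 0.0949 to 1.08 CPM in st61. These genes were chosen after their values were seen. Pigment cell genes (3 of 10 higher, also 3 adjusted over the list alone, camera adjusted p = 0.0895) passed with fry (0.029), the replicate block (0.045), the T3 libraries summed (0.04), thinned libraries (0.029) and the length correction (0.049), and without st61 replicate 3 (0.036). Bile acid genes (6 of 20 higher and 1 lower, 9 and 3 adjusted over the list alone, camera adjusted p = 0.0653) passed without the low-count filter (0.026), with the T3 libraries summed (0.04) and without st54 replicate 3 (0.046) or st61 replicate 3 (0.036). Cholesterol synthesis (camera adjusted p = 0.143) passed, higher, without st66 replicate 2 (0.031) or 3 (0.019) and with st66 replicate 1 alone (2.1e-05), and globins (0.143) without st61 replicate 3 (0.035) or st66 replicate 1 (0.022). Endoplasmic reticulum folding (0.291) passed, higher, without st66 replicate 3 (0.023) and with st66 replicate 1 alone (0.00077), and amino acid breakdown (0.281) passed, lower, with st66 replicate 1 alone (0.036) and with the length correction (0.049). Hormone receptors and coregulators (0.0784) passed, lower, without st54 replicate 3 (0.047). Fatty acid oxidation (0.132) passed, higher, without st61 replicate 3 (0.025), as did immediate early and heat shock genes (0.132) without st66 replicate 1 (0.048).

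Respiratory chain (camera adjusted p = 4.09e-06) and ribosomal protein (1.95e-06) lists were higher at st66 than at st61, each with adjusted p = 0.86 with an estimated correlation and fry adjusted p of 0.276 and 0.375. In edgeR 0 of 70 and 2 of 76 genes passed, and 0 of each adjusted over the list alone (17 and 12 at an unadjusted p under 0.05, 3 and 3 by DESeq2). With st66 replicate 1 alone, again a single library, the respiratory chain list turned lower (adjusted p = 0.89) and the ribosomal list lower (3e-10), and the length correction ended the respiratory call (0.69). Mitosis did not pass (camera, lower, adjusted p = 0.065, with a median log2 change of 0.30 in the other direction) but passed, lower, with the replicate block (adjusted p = 0.037) and without st66 replicate 1 (5e-20), and was higher with that replicate alone (3.7e-25). DNA replication did not pass (0.962), but was higher with st66 replicate 1 alone (9.3e-17) and lower without it (4.6e-06). mki67, a proliferation marker, was at 55.1 ± 3.18 CPM in st61 and 51.7 ± 62.2 CPM in st66.

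In all, 868 genes rose and 647 fell from st61 to st66. 378 genes peaked at st61, such as thibz, cxcl14, a chemokine, and lamb3, a laminin chain, and 338 had a trough there, such as cyp7a1, bbox1 and sult2b1. Only the groups compared gave 181, 170, 130 and 110 in that order, the T3 libraries summed gave 257, 231, 136 and 99, and DESeq2 gave 1330 rises, 1194 falls and 645 peaks. With st66 replicate 1 alone there were 1377 rises and 521 troughs. Leaving out a library moved these counts as follows, in the order rises, falls, peaks and troughs: without st66 replicate 1 to 2478, 2084, 839 and 863, without st61 replicate 1 to 441, 377, 221 and 176, and without st61 replicate 2 to 278, 308, 174 and 93. Without st66 replicate 2 there were 505 rises, 322 falls and 199 peaks, and without st66 replicate 3 there were 380 falls and 234 peaks. Without st54 replicate 3 there were 1322 rises and 1028 falls. Without T3 replicates 1, 2 and 3 in turn there were 405, 404 and 406 falls, 225, 226 and 228 peaks and 220, 220 and 221 troughs, and without T3 replicate 3 there were 578 rises. Both comparisons behind a peak or trough use the st61 libraries, with opposite sign, so spread in st61 alone pushes genes into these counts. How many peaks and troughs it would bring was not estimated.

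In stage 54 tadpoles, 18 h of T3 raised thyroid hormone response genes, several of which were also high at the climax. thrb rose from 1.02 ± 0.551 to 24.3 ± 0.345 CPM (22.2-fold, adjusted p = 1.44e-05), nfic to 52.1 ± 0.99 CPM (11.9-fold) and bcl6 to 82.4 ± 0.888 CPM (5.58-fold). klf9, a zinc finger gene of the early response, rose from 7.90 ± 1.97 to 37.6 ± 0.974 CPM, thibz to 59.0 ± 1.3 CPM and dio2 3.67-fold. Of 11 direct response genes 7 rose, also 7 adjusted over the list alone (camera adjusted p = 3.93e-06, and adjusted p = 0.025 with an estimated correlation). dio3 was at 353 ± 6.69 CPM against 794 ± 290 and did not pass (adjusted p = 0.163), but passed when only the groups compared were fitted (0.027), without st66 replicate 1 (0.04) or st66 replicate 3 (0.035) and with st66 replicate 1 alone (0.01). mmp9.2, a gelatinase gene, rose from 1.24 ± 1.49 to 129 ± 1.37 CPM, and ccl4, a chemokine, from 0.736 ± 0.163 to 44.4 ± 0.936 CPM (adjusted p = 7.47e-08). atp4a, the proton pump subunit of the stomach, was at 11.4 ± 0.651 CPM against 3 reads in the st54 libraries together, with a 95% counting interval of the ratio from 83.8 to 1190.

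Protein folding genes rose with T3: 16 of 33 genes of the endoplasmic reticulum list (22 adjusted over the list alone), among them dnajb9, an induced cochaperone (4.83-fold), and syvn1 and derl2, of the degradation machinery (1.96-fold and 3.37-fold). The list had a camera adjusted p of 9.25e-10, and an adjusted p = 0.61 with an estimated correlation. slc1a4, a neutral amino acid transporter, rose from 7.37 ± 11.3 to 328 ± 3.37 CPM. In the Wnt list 6 genes rose and 3 fell, the same counts adjusted over the list alone (camera adjusted p = 0.233), with axin2 11.8-fold higher.

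Some metabolic genes fell with T3. Of 19 gluconeogenesis and glycogen genes 5 fell (7 adjusted over the list alone), pklr, liver pyruvate kinase, from 258 ± 22.2 to 147 ± 2.36 CPM (camera adjusted p = 0.0026, and adjusted p = 0.61 with an estimated correlation). Of 17 urea cycle and nitrogen genes 5 fell, also 5 adjusted over the list alone (the list did not pass, camera adjusted p = 0.0937, adjusted p = 0.71 with an estimated correlation, and 0.025 without st54 replicate 1), among them glud1 (2.23-fold), got1, a transaminase (2.03-fold), and gls2 (28.4 ± 14.4 to 7.11 ± 0.0442 CPM). cps1 stood at 1013 ± 3.97 CPM and did not pass (adjusted p = 0.116), but passed with DESeq2 (0.032) and without st54 replicate 3 (0.032). rxrg, a partner of the thyroid hormone receptors, fell 2.94-fold, and ddit4, a stress-induced inhibitor of growth signalling, 12-fold. Of 26 cholesterol synthesis genes 3 fell, also 3 adjusted over the list alone (camera adjusted p = 0.0282, adjusted p = 0.71 with an estimated correlation, fry adjusted p = 0.368, 0.1 without st54 replicate 1, 0.096 without st54 replicate 2). cyp7a1 was at 67.5 ± 0.114 CPM (16.4-fold lower, adjusted p = 0.0168), a call that ended without st54 replicate 1 (0.05) or 2 (0.053) and without T3 replicate 1 (0.072), 2 (0.074) or 3 (0.075). Amino acid breakdown, lipogenesis, bile acid and fatty acid oxidation lists did not pass. Of 45 amino acid breakdown genes 4 rose and 6 fell, the same counts adjusted over the list alone (camera adjusted p = 0.233). Of 28 lipogenesis genes 3 rose and 1 fell, the same counts adjusted over the list alone (camera, higher, adjusted p = 0.233). Of 20 bile acid genes 3 rose and 5 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.233). Of 29 fatty acid oxidation genes 1 rose and 4 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0975, and 0.025 without st54 replicate 1).

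Ribosomal protein genes were lower as a list (median log2 change -0.81, camera adjusted p = 1.36e-11), as were respiratory chain genes (camera adjusted p = 1.17e-06), each with adjusted p = 0.71 with an estimated correlation, and the second missed the threshold without st54 replicate 3 (0.098). In edgeR 0 of 76 ribosomal protein genes passed, over all genes or adjusted over the list alone (64 lower at an unadjusted p under 0.05, 6 by DESeq2, fry adjusted p = 0.229). 4 of 70 respiratory chain genes were lower in edgeR (0 adjusted over the list alone, 27 at an unadjusted p under 0.05, 15 by DESeq2, fry adjusted p = 0.264). The share of ribosomal protein reads was 6.66% to 7.35% in the T3 libraries, against 8.56% to 12.5% in st54. Within T3, within st54 and within st61 the deeper libraries had the lower share, and most T3 libraries were deeper than those of st54. At similar totals, T3 replicate 3 (27665558 counts) had 7.35% and st54 replicate 2 (29387091 counts) 8.56%, but this is 1 library each. For the ribosomal genes, depth and T3 can therefore not be told apart. The lymphocyte list was lower (2 of 26 genes, 1 adjusted over the list alone; camera adjusted p = 0.0438, adjusted p = 0.71 with an estimated correlation, fry adjusted p = 0.272). It missed the threshold with T3 libraries summed (0.057), with upper-quartile factors (0.052), with st66 replicate 1 alone (0.072) and without st54 replicate 1 (0.3) or 2 (0.083), st61 replicate 2 (0.051) or 3 (0.064), st66 replicate 1 (0.071), 2 (0.054) or 3 (0.055), or T3 replicate 1 (0.067) or 3 (0.064).

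The plasma protein list missed the threshold with T3, in the direction opposite to that at st61. Of 50 genes 1 was higher and 3 lower (1 and 2 adjusted over the list alone, camera, lower, adjusted p = 0.0522, adjusted p = 0.71 with an estimated correlation, fry adjusted p = 0.272). It passed, lower, without the low-count filter (adjusted p = 0.035), with the replicate block (0.049) and with st66 replicate 1 alone (0.02), and without st54 replicate 1 (0.04) or 3 (0.011), st66 replicate 1 (0.022) or 2 (0.037) or T3 replicate 3 (0.025). Of 20 complement genes 3 were lower (2 adjusted over the list alone, camera adjusted p = 0.0648), and the list passed without the low-count filter (0.047), with the replicate block (0.049) and without st54 replicate 3 (0.00042) or T3 replicate 3 (0.049). Of 30 myeloid markers 1 was higher and 5 lower, the same counts adjusted over the list alone (camera adjusted p = 0.0699), and the list passed, lower, without the low-count filter (0.047) or st54 replicate 3 (0.00042). Of 35 fibroblast markers 2 were higher and 4 lower, the same counts adjusted over the list alone (camera adjusted p = 0.0975, and 0.0034 without st54 replicate 2). Matrix remodelling genes (6 of 24 higher and 2 lower, 7 and 2 adjusted over the list alone, camera adjusted p = 0.193) passed with fry (0.018). Other lists that did not pass were, by camera adjusted p, erythroid cells (0.0891, and 0.0037 without st54 replicate 1), endothelial cells (0.973), bile duct (0.811), exocrine pancreas (0.233, and 0.017 without st54 replicate 1), pigment cells (0.34), skeletal muscle (0.67), globins (0.342), mitosis (0.674), DNA replication (0.116), hepatic detoxification (0.221, and 0.016 without st54 replicate 3) and immediate early and heat shock genes (0.137, and 0.04 without st54 replicate 1).

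In all, 1430 genes were higher and 1140 lower with T3 than without. These counts rest on the closeness of the T3 libraries: with them summed, edgeR called 62 genes higher and 0 lower (1266 and 544 at an unadjusted p under 0.05, and 237 and 93 by DESeq2). Of 45 named genes past the threshold 6 stayed past it with the T3 libraries summed: thrb (adjusted p = 0.0018), nfic (9e-04), bcl6 (0.027), ccl4 (9.2e-05), mmp9.2 (0.016) and atp4a (0.0088). Among those that did not were thibz, dio2 and axin2 (0.062 each), dnajb9 (0.092), klf9 (0.1), slc1a4 (0.13), derl2 (0.17), cyp2u1 (0.18), syvn1 (0.2), ddit4 (0.33) and gls2 (0.34). Of all 2570 calls, 62 (2.4%) were kept. Of the 7 lists called here, lymphocytes lost the call with the T3 libraries summed, while the single T3 library is assumed to vary like the other groups. The higher and lower counts were 546 and 216, 555 and 209, and 537 and 205 without T3 replicates 1, 2 and 3 in turn, 578 and 351 without st54 replicate 1, 673 and 366 without st54 replicate 2, 2249 and 2142 without st54 replicate 3, and 2550 and 2534 without st66 replicate 1. Only the groups compared gave 2412 and 2339, st66 replicate 1 as the only library of its stage 2530 and 2407, and DESeq2 1889 lower.

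**Figure D4:**
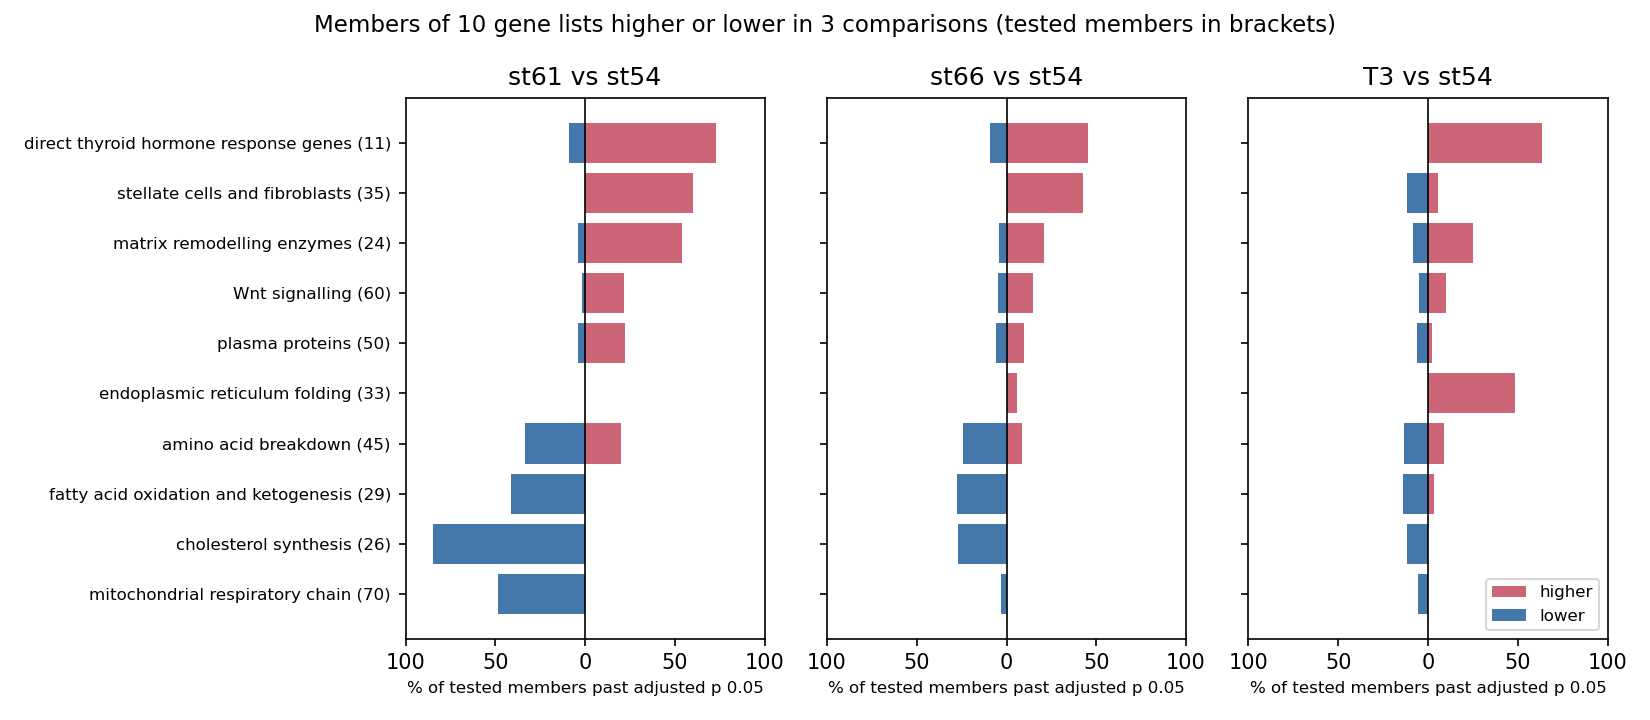
Percentage of the tested members of 10 gene lists that passed the threshold (x axis), higher to the right and lower to the left, in st61, st66 and T3 against st54, n = 3 libraries per group. Direct response genes are mostly higher in st61 and T3 (8 and 7 of 11), fibroblast markers are higher at both later stages (21 and 15 of 35), and endoplasmic reticulum folding genes are higher with T3 (16 of 33).

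T3-treated livers stayed apart from those of the climax. Fibroblast markers were lower than at stage 61 (24 of 35, with 2 higher; 27 and 2 adjusted over the list alone; camera adjusted p = 6.29e-11, and adjusted p = 0.39 with an estimated correlation). Matrix remodelling genes were lower (13 of 24, with 2 higher, the same counts adjusted over the list alone; camera adjusted p = 0.00331, and adjusted p = 0.39 with an estimated correlation), as were plasma protein genes (20 of 50, with 2 higher; 22 and 2 adjusted over the list alone; camera adjusted p = 0.000198, and adjusted p = 0.92 with an estimated correlation). Cholesterol synthesis genes were higher (13 of 26, 19 adjusted over the list alone; camera adjusted p = 5.75e-05). So were endoplasmic reticulum folding genes (16 of 33, 19 and 1 lower adjusted over the list alone; camera adjusted p = 2.1e-05) and fatty acid oxidation genes (11 of 29, 11 and 1 lower adjusted over the list alone; camera adjusted p = 0.0169), each with adjusted p = 0.92 with an estimated correlation. ucp1 was at 94.0 ± 0.273 CPM with T3 and 0.234 ± 0.0483 CPM at st61 (adjusted p = 1.7e-06, and 0.00016 with the T3 libraries summed). The direct response list did not pass between T3 and st61 (camera adjusted p = 0.737). Wnt genes (1 of 60 higher and 12 lower, 1 and 11 adjusted over the list alone, camera adjusted p = 0.0733) passed, lower, without the low-count filter (0.029) or st61 replicate 1 (0.031). Apoptosis (0.0733) passed, higher, without the low-count filter (0.023) and with fry (0.019). Immediate early and heat shock genes (0.0716) passed, higher, with upper-quartile factors (0.049), without the low-count filter (0.039), with fry (0.0496) and without st61 replicate 1 (0.03) or st66 replicate 3 (0.039). Intestinal epithelium (0.975) and pigment cells (0.258) passed with fry alone (0.00297 and 0.0216).

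Endothelial markers were lower with T3 than at st61 (9 of 29, also 9 adjusted over the list alone; camera adjusted p = 0.0255), as was the ribosomal protein list (camera adjusted p = 4.77e-07). Every T3 library was deeper than every st61 library, so for the ribosomal list depth and group cannot be told apart. Camera placed mitosis (adjusted p = 0.00715) and the respiratory chain (0.00331) higher, each with adjusted p = 0.97 with an estimated correlation. Few members of these lists passed. 1 of 76 ribosomal protein genes was lower, 4 of 46 mitosis genes and 12 of 70 respiratory chain genes were higher. In edgeR 0 of each passed adjusted over the list alone. At an unadjusted p under 0.05 there were 33, 8 and 21, and DESeq2 called 16, 5 and 16 over all genes, while fry gave adjusted p = 0.209, 0.404 and 0.279. Without st61 replicate 2 the fatty acid oxidation (0.091), respiratory chain (0.091) and endothelial (0.1) calls ended, the last also with fry (0.11). 2509 genes were higher and 2507 lower with T3 than at st61. With the T3 libraries summed the counts were 376 and 243, with 12.2% of the calls kept and the same 10 lists called, and with only the groups compared 4569 and 4451. They were 1596 and 1546, 1597 and 1521, and 1582 and 1529 without T3 replicates 1, 2 and 3 in turn, and the higher count was 1602 without st61 replicate 2.

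Of the 2570 genes changed by T3, 600 (23.3%) changed the same way between st54 and st61, 329 upward, such as thrb, nfic and bcl6, and 271 downward, such as glud1. Independent lists of these sizes would share 143.5 genes upward and 100.9 downward. The downward part, glud1 included, rests on the closeness of the T3 libraries: with them summed, edgeR left no gene called lower with T3. Both comparisons use the st54 libraries, which are too few to be split with 2 in each part. In 20 simulations without any effect, edgeR found a mean of 0 genes the same way (158 at an unadjusted p under 0.05). Hardly any gene passes where no gene has an effect, so that 0 was close to fixed beforehand. It does not show how much of the overlap the shared controls bring, and part of the excess may come from them. The simulations also gave all groups the same spread per gene, unlike the libraries (33.5% in st54, 2.6% in T3). The simulated covariance is therefore a rough baseline. The covariance of the log2 changes was 0.26 against 0.076 ± 0.0036 (SD over 20 simulations), a difference of 0.184, and Pearson's r across genes was 0.261 against 0.509 in the simulations. The count of 600 was 40 with the T3 libraries summed, 1245 with only the 3 groups compared and 1239 with st66 replicate 1 as the only library of its stage. It was 242, 242 and 243 without T3 replicates 1, 2 and 3 in turn, 254 without st54 replicate 1, 267 without st54 replicate 2, 1372 without st54 replicate 3, 376 without st61 replicate 2 and 1304 without st66 replicate 1.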

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

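The test for repeat libraries of 1 RNA pool was chosen only after the closeness of the T3 libraries had been seen, as were the sum of the T3 libraries and the counts of opposite genes under each setting.

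119 genes changed in opposite directions at stage 61 and under T3, both against stage 54, and stand here because the response to the hormone and the change at the climax differ in sign. Of these, 60 were higher at st61 and lower with T3, and 59 the reverse. Independent lists would share 241 opposite genes, a value that leaves out the shared st54 libraries, which push changes to the same sign. With those controls and no effect, edgeR gave a mean of 0 opposite genes over 20 simulations (1.4 at an unadjusted p under 0.05). That 0 was close to fixed beforehand, since hardly any gene passes without an effect. With the T3 libraries summed edgeR called 0 opposite genes (113 at an unadjusted p under 0.05, 11 by DESeq2). The count was 27, 26 and 24 without T3 replicates 1, 2 and 3 in turn, 30, 38 and 179 without st54 replicates 1, 2 and 3, 56 and 53 without st61 replicates 1 and 2, and 384 without st66 replicate 1. gls2, liver glutaminase, was the only named gene among them: 28.4 CPM at st54, 71.3 at st61 and 7.11 with T3, with a log2 change of -3.32 between T3 and st61 (adjusted p = 0.00031 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and with the T3 libraries summed its T3 vs st54 (adjusted p = 0.34) and st61 vs st54 (0.092) calls both ended.

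The T3 libraries lay closer together than those of any other group (biological coefficient of variation 2.6%). Their greater depth is argued against: thinned to the smallest total, the T3 libraries still varied by 3.2%, against 32.2%, 23.0% and 39.6% in st54, st61 and st66. An evening-out of the tadpoles at the genes the hormone changes is also argued against, since among the 12532 genes not past T3 vs st54 the median SD of log2 CPM was 0.058 in T3 and 0.323 in st54. Repeat libraries or aliquots of 1 RNA pool stay open: the lowest chi-square per gene between T3 libraries was 1.99, above sampling noise but far below the 14.3 or more of other groups, and the counts do not tell repeat libraries from very similar animals. If they were aliquots, the T3 p-values would measure technical spread on the T3 side.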

How the results depend on the processing

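The sum of T3 libraries, the length correction, the thinning and the use of st66 replicate 1 alone were tests chosen after seeing the data. Replicate numbers did not pair the samples (18 same-number pairs with correlations from -0.11 to 0.158, 1 of them over 0.1, and 5 of 12 libraries closest to their own number). With the replicate block, genes lower in T3 vs st54 numbered 696 and opposite genes 73, and no other count of genes or lists moved by over 1.5 times. DESeq2 gave 1249 lower in st66 vs st54, 1330 higher and 1194 lower in st66 vs st61, 1889 lower in T3 vs st54, 230 opposite genes and 645 peaks. There were 72 opposite genes without the low-count filter and 72 in thinned libraries. Only the groups compared gave 296 and 271 in st66 vs st54, 181 and 170 in st66 vs st61, 2412 and 2339 in T3 vs st54, 4569 and 4451 in T3 vs st61, 1245 changed the same way, 386 opposite, 130 peaks and 110 troughs. T3 libraries summed gave 1010 and 649 in st61 vs st54, 591 and 477 in st66 vs st54, 257 and 231 in st66 vs st61, 62 and 0 in T3 vs st54 (edgeR, 1266 and 544 at an unadjusted p under 0.05, DESeq2 237 and 93), 376 and 243 in T3 vs st61, 40 the same way, 0 opposite (113 unadjusted, DESeq2 11), 136 peaks and 99 troughs: a single library leaves that group no spread of its own. With st66 replicate 1 alone there were 2219 lower in st61 vs st54, 1377 higher in st66 vs st61, 2530 and 2407 in T3 vs st54, 1239 the same way, 371 opposite and 521 troughs, again with no spread of its own for that group. With an estimated correlation 2, 0, 0, 1 and 0 lists passed in the 5 comparisons (4, 1, 2, 2 and 2 at an unadjusted p under 0.05), and with fry 8 in st66 vs st54 and 5 in st66 vs st61.

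Leaving out 1 library in turn, the higher and lower counts ran from 1062 to 2193 and 658 to 2238 in st61 vs st54, 712 to 2333 and 557 to 1899 in st66 vs st54, 278 to 2478 and 308 to 2084 in st66 vs st61, 537 to 2550 and 205 to 2534 in T3 vs st54, and 1582 to 3540 and 1521 to 3452 in T3 vs st61. Genes changed the same way ran from 242 to 1372, opposite genes from 24 to 384, peaks from 174 to 839 and troughs from 93 to 863. Lists past the threshold ran from 8 to 12, 8 to 17, 9 to 14, 6 to 11 and 7 to 12. Directions turned with st66 replicate 1 alone for DNA replication (adjusted p = 2e-07), mitosis (1.3e-05) and ribosomal proteins (5.2e-11) in st66 vs st54, and for mitosis (3.7e-25), respiratory chain (0.89), erythroid (0.0073) and ribosomal (3e-10) lists and mki67 (log2 change 1.17) in st66 vs st61. DNA replication in st66 vs st61 turned without st66 replicate 1 (4.6e-06, with 0.09 to 0.96 without any other library), and ribosomal proteins in st61 vs st54 with the length correction (0.048). Each list was counted once per comparison and setting, and each named gene likewise. Settings other than leaving out 1 library in turn gave 1728 list values on the same side of the threshold. There were 82 lost list calls, 52 gained and 8 turned. For named genes the same counts were 2396, 223, 14 and 1, with 6 more that moved. With 1 library left out these were 1938, 45, 56 and 1 for lists and 2551, 323 and 16 for named genes, with 2 that moved. The first tally includes settings that drop or merge libraries. Of its turned lists 7, and its 1 turned named gene, came from st66 replicate 1 alone. The T3 libraries summed gave 80 of its lost named-gene calls, and only the groups compared gave 48. Of its lost list calls, 47 came from the estimated correlation and 23 from fry. Where not shown by the alternative's own construction, the cause was not tested. The 2 shallowest libraries, at 7928459 and 8506341 counts, limit low genes in st66, where 3 counts are worth 0.378 and 0.353 CPM.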

Other observations

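The test of the share of pancreas, the sum of the T3 libraries and every count of other splits were chosen only after the results had been seen.

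Other genes of the lists changed in opposite directions at st61 and under T3, and were chosen after their values were seen. plin2, which coats lipid droplets, was at 224 CPM in st54, 56.0 in st61 and 518 with T3, and mmp1, a collagenase, at 4.61, 1.07 and 10.1. tagln, a smooth muscle gene, went the other way (15.6, 32.2 and 4.91 CPM), as did slc40a1, the iron exporter (891, 1330 and 579 CPM). T3 vs st61 had adjusted p = 0.00015 for plin2 and mmp1, 0.00011 for tagln and 0.00069 for slc40a1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the T3 libraries summed the T3 vs st54 calls ended (adjusted p = 0.39 for plin2, 0.44 for mmp1, 0.24 for tagln and 0.53 for slc40a1), as did st61 vs st54 for tagln (0.065) and slc40a1 (0.14) and T3 vs st61 for slc40a1 (0.087).

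Hepatic detoxification genes moved both ways between stages: at st61 6 of 45 were higher and 16 lower than at st54 (10 and 16 adjusted over the list alone), and at st66 8 and 11 (11 and 14 adjusted over the list alone, camera adjusted p = 0.211). Of 12 intestinal epithelium genes 3 were higher and 1 lower with T3 than without, the same counts adjusted over the list alone, with a camera adjusted p of 0.375 and a fry adjusted p of 0.000607, which asks only whether the list's genes move on balance to one side. Of 33 apoptosis genes 6 were higher with T3, also 6 adjusted over the list alone (camera adjusted p = 0.135).

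Ribosomal protein genes were higher in st66 replicates 2 and 3 than in replicate 1, by a median log2 difference of 1.58 (95% interval 1.53 to 1.65, 76 genes). The intervals in this paragraph come from resampling genes, which are not independent, and do not cover the spread between libraries. Exonic length bias could account for part of this, since 83 other genes matched on length and CPM differed by 1.16 (0.99 to 1.40). At a median length of 907 bases against 611.5 the match is loose. Those genes were also densely covered (median 1030 CPM per kb of exon), so the match does not tell length from density. Loss of reads at densely covered genes in the deeper library stays open, since 86 genes matched on reads per kb differed by 0.99 (0.78 to 1.34) at a lower median density (1210 against 1830). No biological explanation was tested.

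Exocrine pancreas genes differed between stages in both directions. A varying share of pancreas tissue in the samples cannot be told apart from a pancreas that changes its own genes: outside the trypsin and elastase families, whose copies can take each other's reads, 5 members were lower at st66 and 1, cel, a lipase, was higher than at st54, too few to decide. Reads shared between elastase genes could account for opposite changes within that family at st61. The summed CPM of 9 elastase genes was 0.987 times that at st54 (621.8 ± 525 against 629.9 ± 476). The libraries ran from 232 to 1220 CPM at st61 and from 157 to 1110 at st54. With that spread a ratio near 1 does not show that the sum was kept, so shared reads stay open. At st66 the sum was lower, at 171 ± 170 CPM (32.6 to 361), but the libraries overlapped those of st54, and shared reads stay open there too. Reads shared between trypsin genes cannot be told apart from a change of expression, because the sum of 4 trypsin genes was 16.4 times higher at st61 but the libraries overlapped (7.03 to 60.9 CPM at st54 and 53.1 to 1030 at st61).

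The 6 libraries of each comparison of 2 groups allow 10 splits, too few for a share under 0.05. Counting the real one, 1 of 10 splits gave as many changed genes in each comparison. The real split and the highest other gave 2853 and 1 genes in st61 vs st54, 2070 and 539 in st66 vs st54, and 1515 and 437 in st66 vs st61, the other splits with 539 and 437 genes being those that set st66 replicate 1 with replicates 1 and 2 of the other group. In T3 vs st54 they gave 2570 and 0 genes and in T3 vs st61 5016 and 0 (edgeR, with 1373 and 220 genes in the highest other split at an unadjusted p under 0.05). For lists past the threshold 8, 3, 6, 10 and 7 of the 10 splits gave as many in the 5 comparisons. The order is st61 vs st54, st66 vs st54, st66 vs st61, T3 vs st54 and T3 vs st61. Real values were 9, 14, 10, 7 and 10, and highest others 18, 15, 16, 14 and 14. Lists thus passed in wrong groupings as well, so their number past camera's threshold does not set the real groups apart.

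For results over 3 groups, 30 splits of the 9 libraries were used, and relabelings of whole groups were left out after a first draw had been seen. 2 of 30 splits gave as many genes changed the same way at st61 and under T3 (1245 in the real split, 1619 in the highest other), as many peaks (130 and 139) and as many troughs (110 and 248). The split with 1619 genes kept the 3 T3 libraries together, and the split with 139 and 248 kept the 3 st54 libraries together, so both carry a difference between real groups and point to the structure of the samples. These splits do not exclude chance and do not argue for it.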
